A study of Homo sapiens with 3 samples.

How the data were processed

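RNA was sequenced from 3 SKOV3 libraries: 1 of cells with a control hairpin and 2 of cells with a CBX8 hairpin, 1 per hairpin. SKOV3 is an established human ovarian cancer line; total RNA was harvested with Trizol, and libraries followed standard Illumina protocols, per the labels' protocols. Groups were taken from the treatment label of each sample, which gives the control, CBX8 hairpin 1 or CBX8 hairpin 2.

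The deposited count table holds raw read counts per gene for 60483 genes with versioned Ensembl identifiers, symbols and biotypes. The deposited FPKM table holds FPKM values of the same genes. The submitters' processing notes name Trimmomatic 0.36, STAR 2.6.1d, edgeR 3.22.5 and build hg38 without giving their roles. The counting program, annotation release and strand setting are not given in the sources used here. Checked on the values, deposited FPKM equalled the count divided by a gene length and by the library's total over protein-coding genes, with a largest relative deviation between libraries of 1.6e-05. For 86.1% of 11242 genes the implied length lay within 5% of the summed exon lengths over all transcripts of GENCODE 29. FPKM therefore understates genes with many transcripts, but a gene can be compared across libraries. Reads of near-identical genes, such as PSG3 and its family, HLA genes, histone, ribosomal protein and heat shock genes and genes with processed pseudogenes such as SET and NPM1, could be split or lost in counting, and their values are uncertain. Likewise uncertain are genes that overlap another gene.

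Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 16308, and libraries were scaled by TMM factors of 0.965, 1.003 and 1.034. The knockdown group of 2 libraries was compared with the control by edgeR's quasi-likelihood test at a false discovery rate of 0.05 with Benjamini-Hochberg adjustment, using the dispersion method that sets legacy to FALSE with the top 5% of genes. That fit had 1 residual degree of freedom per gene and 9.25 prior degrees of freedom. The installed version's default is the older method, which called 114 genes against 35. The older method had been named as the alternative before the data were examined, and both counts had been seen before the analysis was made final. The test, samples, gene lists, rule for named genes and alternatives were fixed before the data were examined. Nothing in the labels says that the libraries came from separate cultures. Single-gene p-values thus measure only the spread between these samples, which may be technical.

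Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Log2 folds of single hairpin libraries used a prior count of 2, and a size rule counted genes at 2-fold or more with a mean CPM of 1 or more. Ratios and CPM of CBX8, SUSD2 and SET carry exact Poisson or binomial 95% intervals without a prior count. Chance sharing under 1 common control was estimated from 200 simulations with trended dispersions, which include the differences between hairpins. Those simulations had no further scatter between genes, so their ranges may be too narrow. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 51.9 for control and hairpin 1, 59.3 for control and hairpin 2 and 36.0 between hairpins, so none was a duplicate.

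A set of 41 gene lists with 1332 entries was used, of which 1328 entries matched a gene of the table, and 37 lists had the 5 tested genes needed. The lists were tested with camera at a correlation of 0.01 between genes, with camera at an estimated correlation and with fry, each adjusted over the lists. Each list median was also placed as a percentile among 10000 random lists of the same size, matched on mean expression. The random lists treat genes as independent. Camera at an estimated correlation and fry rest on the 1 residual degree of freedom, which leaves them little power. At the preset correlation camera's p-values rest on the spread between genes, taken as nearly independent. They do not measure the spread between the 3 libraries. Coordinates are those of GENCODE 29 on the hg38 assembly, found by gene identifier without its version for 56753 of the table's genes.

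Genes were named by rule: CBX8, SUSD2 and SET; in each direction the 12 called genes with a mean CPM of 5 or more and the largest smaller-of-both-hairpins fold, filled where fewer passed from genes at 2-fold or more with both hairpins; the 5 genes with the largest fold between hairpins in each direction; and up to 4 genes per list with a mean CPM of 1 or more, same direction first. Names outside the rule are marked where they appear.

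On simulated data with 200 changed genes, over 10 simulations of the knockdown comparison on 15835 genes, the quasi-likelihood test recovered 24.3% of genes raised 2-fold, 97.3% raised 4-fold and 100% raised 8-fold, and 23.3% and 88.3% of genes lowered 2-fold and 4-fold, with 3.90% false calls. The changed genes had a mean CPM of 5 or more, and both simulated hairpins had the same effect. Counts followed the trended dispersion without further scatter between genes, so these rates need not hold for the measured libraries. The alternatives tried were RLE, upper quartile and library size scaling, other filters, DESeq2, the older quasi-likelihood method, the likelihood ratio test, limma on log2(FPKM + 1) and log2(FPKM + 0.1), fold thresholds of 1.5 and 4, and leaving out each knockdown library. A loess correction for GC content and length, a mean CPM of 10 or more, a robust fit and a level of 1 or 10 CPM that weights control and knockdown equally as a geometric mean were added after the data were seen.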

Results

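Gene expression was measured by RNA sequencing in SKOV3 cells, an established human ovarian cancer line, after stable infection with lentivirus carrying a control short hairpin RNA or a hairpin against CBX8. CBX8 is a chromobox subunit of Polycomb repressive complex 1, a chromatin complex that keeps genes silent. The data comprised 1 control library and 2 knockdown libraries, 1 for each of 2 CBX8 hairpins. Total counts over genes were 17533131 in the control, 17880022 with hairpin 1 and 16005361 with hairpin 2, and 23627, 24453 and 24342 genes had at least 1 count. Protein-coding genes took 98.3% of counts in the control, 98.1% with hairpin 1 and 97.8% with hairpin 2, with 95% Wilson intervals narrower than the last digit given. Mitochondrially encoded mRNAs took 2.79% (95% Wilson interval 2.79 to 2.80) in the control, 3.64% (3.63 to 3.64) with hairpin 1 and 3.33% (3.32 to 3.34) with hairpin 2. A count of 0 allows a level of up to 0.171, 0.168 and 0.187 CPM (normalised counts scaled to library size), taken as 3 counts of the total. These intervals and limits cover counting error only.

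The first question was whether the hairpins lowered their target and what happened to the genes of the series title, which links CBX8 and SET, a histone chaperone, to suppression of SUSD2, a sushi domain membrane protein. CBX8 (ENSG00000141570.9; hg38 chromosome 17, 79792132 to 79801683, minus strand) had 12.8 CPM in the control (95% counting interval 11.2 to 14.7), 4.80 CPM with hairpin 1 (3.84 to 5.93) and 4.30 CPM with hairpin 2 (3.36 to 5.42). It was thus 62.6% and 66.5% lower than in the control. SUSD2 (ENSG00000099994.10; chromosome 22, 24181259 to 24189110, plus strand) had 5 counts in the control, 99 with hairpin 1 and 32 with hairpin 2, or 0.296, 5.53 and 1.94 CPM. The ratio to the control was 18.7 with hairpin 1 (95% counting interval 7.74 to 58.8) and 6.55 with hairpin 2 (2.53 to 21.5). Among 13986 genes with a mean CPM of 1 or more, SUSD2 ranked 46 by the smaller of its upward folds and CBX8 ranked 21 by the smaller of its downward folds. SET (ENSG00000119335.15; chromosome 9, 128683424 to 128696400, plus strand) had 889, 676 and 778 CPM, which was 24.0% lower with hairpin 1 and 12.5% lower with hairpin 2.

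In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, none of the 3 passed the threshold. The log2 fold change was -1.49 (SE 0.37, adjusted p = 0.183) for CBX8, 3.63 (SE 0.93, adjusted p = 0.193) for SUSD2 and -0.29 (SE 0.27, adjusted p = 0.713) for SET. Adjusted over the list alone, that is over these 3 genes, the values were 0.00427 for CBX8, 0.00427 for SUSD2 and 0.315 for SET. The series title that names SUSD2 may itself rest on these libraries, so its value over the list alone is not an independent test. With edgeR's likelihood ratio test, which made more false calls on simulated data, CBX8 and SUSD2 passed over all genes (adjusted p = 0.0427 and 0.00722). Neither passed with any other fit tried. The adjusted p was 0.223 for CBX8 and 0.0865 for SUSD2 with DESeq2, and 0.0706 and 0.0604 with the older quasi-likelihood method. SUSD2 rested on few counts in the control, and its log2 fold was 3.77 with hairpin 1 and 2.32 with hairpin 2, so it was higher in both knockdown libraries by unequal amounts. An antisense gene overlaps CBX8 in the annotation, and the strand setting of the counting is not given in the sources used here.

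**Figure D1:**
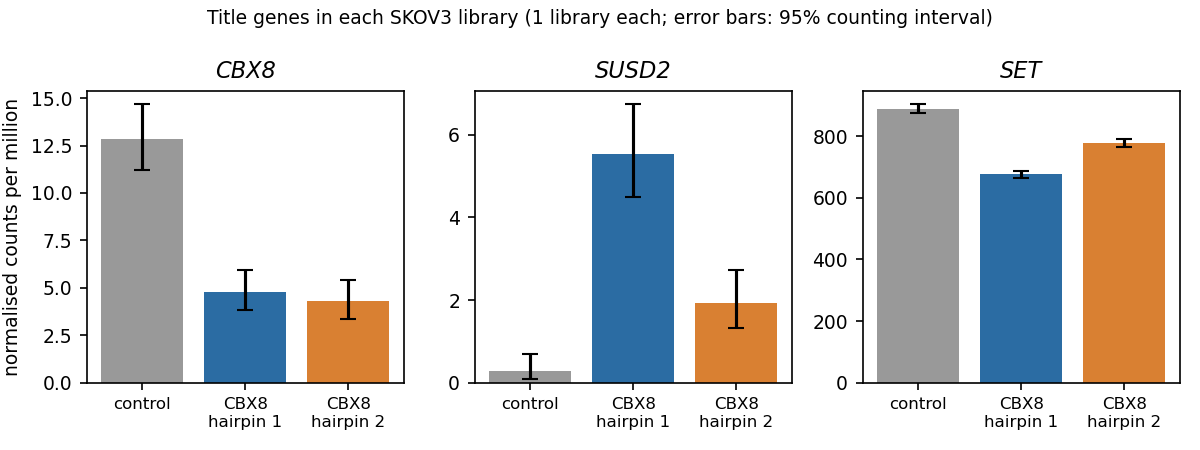
Bars show the CPM of CBX8, SUSD2 and SET in the control, hairpin 1 and hairpin 2 libraries, 1 library each, with axes starting at 0 and separate scales; error bars are 95% counting intervals. CBX8 stood at 12.8, 4.80 and 4.30 CPM, and SUSD2 at 0.296, 5.53 and 1.94 CPM.

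Across all genes, the knockdown libraries were compared with the control to find genes whose RNA level differed. Of 16308 genes tested, 30 rose and 5 fell, and each of the 35 differed at least 2-fold in the same direction with both hairpins. Among called genes with a mean CPM of 5 or more, PSG3, a pregnancy-specific glycoprotein, rose most by the smaller of its folds. It went from 1.54 CPM to 41.7 and 19.98 CPM (log2 fold change 4.32, SE 0.55, adjusted p = 0.0342). The ubiquitin ligase gene TRIM2 rose from 6.69 CPM to 65.4 and 48.5 CPM, and LCN2, which encodes the siderophore-binding lipocalin 2, from 2.604 CPM to 39.4 and 19.3 CPM. The cyclin-dependent kinase inhibitor CDKN1C rose from 3.37 CPM to 43.8 and 22.5 CPM. IGFN1 was the most abundant of the 12 genes taken by rank, rising from 66.6 CPM to 671 and 395 CPM. The others among the 12 were SULT1C2, a sulfotransferase, GPRC5C, RAPGEF3, a cyclic AMP-activated exchange factor, DPP4, a cell-surface peptidase, ASS1, an arginine synthesis enzyme, CRYAB, a small heat shock protein, and LINC01111. Their fitted log2 fold changes ran from 2.77 for CRYAB to 3.40 for DPP4.

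Among genes that fell, SGK1, a serum- and glucocorticoid-regulated kinase, dropped from 100.4 CPM to 13.7 and 26.1 CPM (log2 fold change -2.33, SE 0.33, adjusted p = 0.0374). RRM2, a ribonucleotide reductase subunit that supplies deoxynucleotides, dropped from 482 CPM to 114 and 158 CPM (-1.83, SE 0.26, adjusted p = 0.0374). TRIB2, a pseudokinase, had 15.3, 2.23 and 3.33 CPM (-2.46, SE 0.40, adjusted p = 0.0491), and BNIP3, a hypoxia-induced mitophagy receptor, had 174, 68.2 and 61.7 CPM (-1.42, SE 0.23, adjusted p = 0.0491). The fifth, SERPINB7, lies outside the naming rule because of its low mean level and was added after its values were seen; it had 60, 4 and 2 counts. Other genes at 2-fold or more below the control with both hairpins did not pass the test; those taken by rank at a mean CPM of 5 or more were RP11-214O1.2, MT2A, FGF1, CBX8, TOX, MARCH4, MOK and ZNF492, with log2 fold changes of -1.93 for FGF1, -1.70 for TOX and -1.23 for ZNF492. The metallothionein MT2A had 1057 CPM in the control, 394 with hairpin 1 and 337 with hairpin 2 (adjusted p = 0.0529).

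The call count depended on the method: without a filter on low counts edgeR called 0 genes (1608 at an unadjusted p under 0.05), DESeq2 called 99 higher and 14 lower, edgeR's older quasi-likelihood method 97 higher and 17 lower, and limma on deposited FPKM 0 (2778 at an unadjusted p under 0.05 on log2(FPKM + 1)). With 1 residual degree of freedom, drawn from the difference between hairpins, and a lone control assumed to vary like the knockdown libraries, the p-values measure the spread between these samples.

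**Figure D2:**
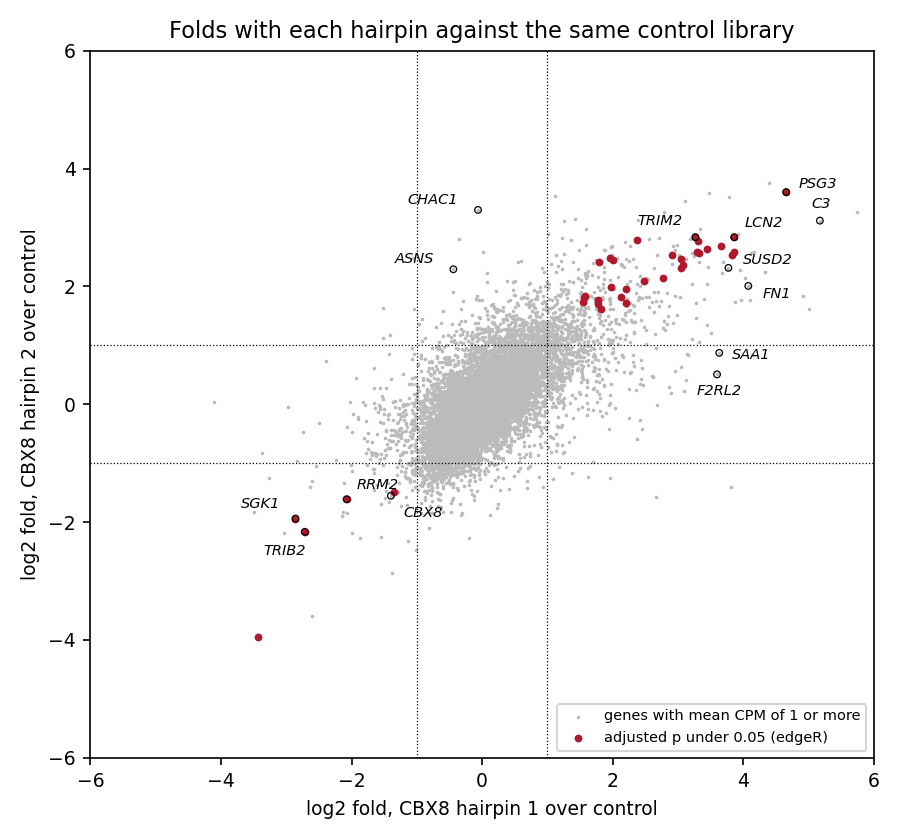
Each point is a gene with a mean CPM of 1 or more; the x axis is its log2 fold with hairpin 1 and the y axis its log2 fold with hairpin 2, both over the same control library, and dotted lines mark 2-fold. Red points are genes with an adjusted p under 0.05, 30 at the upper right and 5 at the lower left; CHAC1 and ASNS lie high with hairpin 2 alone, SAA1 and F2RL2 with hairpin 1 alone.

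Both folds share 1 control library, which bears on each count of list members given below. Across genes with a mean CPM of 1 or more, 75.6% had the same direction with both hairpins. Simulated unchanged libraries gave 66.7%. Cell cycle genes were lower with both hairpins. Of 44 G1/S and replication genes tested, 44 lay below the control with both hairpins, with a median log2 fold change of -0.85 (-0.61 with hairpin 1, -1.19 with hairpin 2). RRM2 fell over all genes tested, and 35 fell adjusted over the list alone. MCM10, a replication initiation factor, had 90.8 CPM in the control, 47.3 with hairpin 1 and 28.3 with hairpin 2, and the origin licensing factor CDC6 had 197, 102 and 75.9 CPM. Of 51 G2/M and mitosis genes, 50 lay below the control with both hairpins (median -0.77); 0 fell over all genes and 48 fell adjusted over the list alone. Cyclin A2, encoded by CCNA2, had 226, 129 and 68.5 CPM, and the spindle checkpoint gene MAD2L1 had 134, 68.2 and 49.0 CPM. With a preset correlation the camera test gave adjusted p = 1.11e-32 for G1/S genes and 3.09e-33 for G2/M genes. Both lists had adjusted p = 0.644 with an estimated correlation. Values at the preset correlation rest on the spread between genes, not between libraries.

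Genes of growth and energy metabolism were also lower. All 38 ribosome biogenesis genes and MYC targets tested lay below the control with both hairpins (median -0.59, adjusted p = 1.22e-15, but 0.644 with an estimated correlation), and 8 fell adjusted over the list alone; the nucleolar helicase gene DDX21 had 610, 324 and 358 CPM. Of 34 hypoxia and glycolysis genes, 25 lay below the control (median -0.54, adjusted p = 1.39e-09, but 0.644 with an estimated correlation), BNIP3 fell over all genes and 9 fell adjusted over the list alone; hexokinase 2, encoded by HK2, had 32.8, 10.6 and 17.8 CPM. Of 30 homologous recombination and Fanconi genes, 24 lay below the control (median -0.46, adjusted p = 1.16e-07, but 0.644 with an estimated correlation) and 3 fell adjusted over the list alone. Sterol synthesis genes (29 tested, median -0.47, adjusted p = 0.000232), nuclear-encoded respiratory chain subunits (43 tested, median -0.34, adjusted p = 0.000531), histone chaperones (16 tested, median -0.31, adjusted p = 0.000355), cytosolic ribosomal proteins (76 tested, median -0.18, adjusted p = 0.00337), subunits of Polycomb repressive complex 2 (11 tested, median -0.29, adjusted p = 0.0365) and developmental transcription factors (45 tested, median -0.31, adjusted p = 0.0365) were called lower with 0 members falling over all genes or over the list alone. With an estimated correlation the adjusted p was 0.676 for complex 2, 0.772 for the respiratory chain and for ribosomal proteins, and 0.644 for sterol synthesis, histone chaperones and developmental factors. Among the matched random lists, the ribosomal protein median stood at percentile 9.375 (31.745 with hairpin 1, 6.74 with hairpin 2). Complex 2 stood at 6.335 (7.85 and 4.395), so a share of random lists lay as low as these 2 lists. Histone chaperones stood at 1.61, and sterol synthesis, the respiratory chain and developmental factors at 0. The histone chaperone median was -0.52 without hairpin 1, and the respiratory chain median -0.22 without hairpin 2. Among the histone chaperones, CHAF1A and CHAF1B are also on the G1/S list and NPM1 is also on the ribosome biogenesis list. In the respiratory chain list COX7C lay the other way, at 27.2, 76.0 and 66.0 CPM. Among developmental factors DLX3 (0.473, 6.37 and 2.85 CPM) and TBX15 (1.42, 4.91 and 3.57 CPM), chosen after their values were seen, were 2-fold or more higher with both hairpins, and 0 were 2-fold lower with both. EZH2, the methyltransferase of Polycomb repressive complex 2, had 106 CPM in the control, 79.3 with hairpin 1 and 50.2 with hairpin 2.

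Ovarian carcinoma markers, immune genes and epithelial genes were higher. Of 18 ovarian carcinoma and Muellerian markers tested, 15 lay above the control with both hairpins (median 0.95, adjusted p = 3.7e-13, but 0.644 with an estimated correlation); LCN2, CLDN4 and L1CAM rose over all genes, L1CAM being outside the naming rule, and 10 rose adjusted over the list alone. Of 45 interferon-stimulated genes, 36 lay above the control (median 0.81, adjusted p = 1.32e-13, but 0.644 with an estimated correlation); 0 rose over all genes and 11 rose adjusted over the list alone. TRIM22 had 0.296, 5.58 and 4.60 CPM, and the guanylate-binding protein gene GBP1 had 0.888, 8.60 and 5.45 CPM. Of 19 antigen presentation genes, 18 lay above the control (median 0.81, adjusted p = 1.9e-12, but 0.644 with an estimated correlation); 0 rose over all genes and 13 rose adjusted over the list alone. The immunoproteasome subunit PSMB9 had 1.78, 18.8 and 9.93 CPM, and HLA-B had 6.15, 30.2 and 18.8 CPM. Of 34 epithelial genes, 23 lay above the control (median 0.51, but 0.27 without hairpin 2; adjusted p = 1.16e-07, but 0.644 with an estimated correlation); the tight junction genes CLDN4 and CLDN1 rose over all genes, CLDN1 being outside the naming rule, and 11 rose adjusted over the list alone. CLDN4 had 4.56, 25.9 and 19.7 CPM, and E-cadherin, encoded by CDH1, had 2.31, 10.1 and 10.8 CPM. CLDN4 is on both the ovarian and the epithelial list, as are CLDN3, EPCAM and KRT7, which are outside the naming rule. The lists are thus not independent.

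Smaller shifts upward were found in NF-kB targets and cytokines (30 tested, median 0.49, adjusted p = 3.52e-06, 3 rising adjusted over the list alone), integrin subunits (16 tested, median 0.34, adjusted p = 0.000868, 2 rising adjusted over the list alone), proteases and their inhibitors (28 tested, median 0.31, adjusted p = 0.0452) and unfolded protein and integrated stress response genes (35 tested, median 0.34, adjusted p = 0.0158), and 0 members of these lists rose over all genes. With an estimated correlation the adjusted p was 0.763 for the stress response list and 0.644 for the others. Complement C3 had 21.9 CPM in the control, 795 with hairpin 1 and 191 with hairpin 2 (log2 fold change 4.49, adjusted p = 0.0529), and integrin subunit ITGB3 had 4.38, 17.2 and 25.5 CPM. The median of the NF-kB list was 0.68 with hairpin 1 and 0.14 with hairpin 2. The median of the stress response list was -0.062 with hairpin 1 and 0.65 with hairpin 2. In all, 8 of 37 lists were called higher and 11 lower with a preset correlation, and 0 with an estimated correlation or with fry, which tests whether a list's genes move on balance one way. Both of these alternatives rest on 1 residual degree of freedom and had little power, so their 0 calls decide neither for nor against a shift. The preset correlation is an assumption, and p-values under it treat genes as nearly independent.

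**Figure D3:**
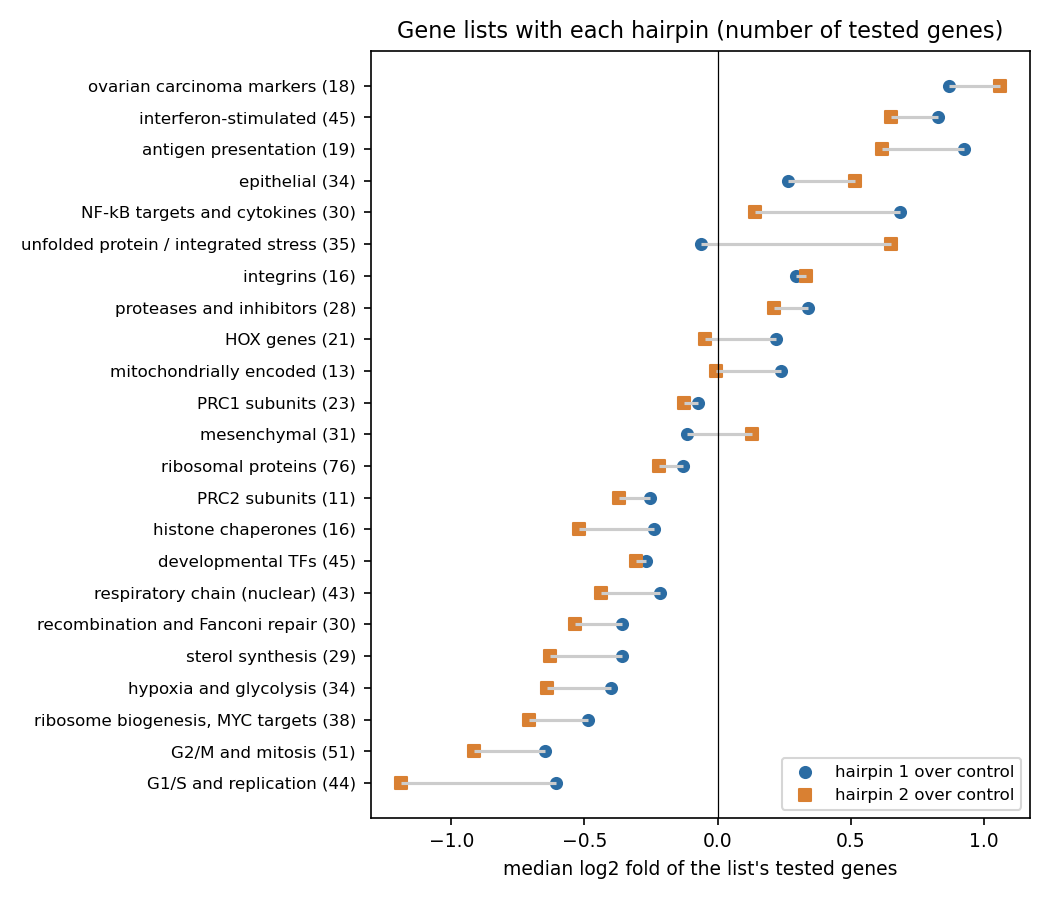
Median log2 fold of the tested genes of each list shown with hairpin 1 (circles) and hairpin 2 (squares) over the control library; the number of tested genes stands in brackets. G1/S genes lie at -0.61 and -1.19 and ovarian carcinoma markers at 0.87 and 1.06; the stress response list spans 0.

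HOX genes, classical Polycomb targets, were not called (21 tested, median 0.14, but 0.22 with hairpin 1 and -0.048 with hairpin 2; adjusted p = 0.573); HOXB9 had 129, 187 and 228 CPM. Polycomb repressive complex 1 subunits were not called either (23 tested, median -0.11, adjusted p = 0.136), and CBX8 was their 1 member to fall adjusted over the list alone. Developmental transcription factors, the other classical Polycomb targets listed, were called lower with a preset correlation, as given above (median -0.31). Of 45 tested, 28 lay below the control and 9 above it with both hairpins. The cyclin-dependent kinase inhibitor and RB family list had a median of -0.11 and a mean of 0.40 (8 tested, median -0.24 with hairpin 1 and -0.070 with hairpin 2, adjusted p = 0.277); CDKN1C rose over all genes and CDKN1B, which encodes p27, had 20.2, 46.9 and 45.5 CPM. Mesenchymal genes had a median of -0.13 (-0.12 with hairpin 1 and 0.13 with hairpin 2) while their mean was 0.29 and the test pointed upward (31 tested, adjusted p = 0.293, 5 rising adjusted over the list alone). Fibronectin, encoded by FN1, had 53.9, 912 and 217 CPM, and COL1A1 had 8.70, 48.1 and 30.6 CPM (adjusted p = 0.0529). Lists of p53 targets (median 0.020, adjusted p = 0.837), apoptosis genes (0.0060, 0.846), Wnt (0.034, 0.837), TGF-beta and BMP (0.059, 0.837), Notch (0.11, 0.386), YAP targets (-0.081, 0.173), receptor kinase and MAPK genes (-0.15, 0.105), NRF2 targets and metallothioneins (-0.030, 0.27) and heat shock genes (-0.43, 0.199) were not called. The medians of the apoptosis, NRF2 and YAP lists changed sign under another scaling of the libraries. The heat shock median stood at percentile 0.14 of the matched random lists (9.72 with hairpin 1, 0.01 with hairpin 2). The medians with hairpin 1 and hairpin 2 had opposite signs for the p53 (-0.10 and 0.032), apoptosis (0.13 and -0.059), Wnt (0.080 and -0.081), NRF2 (0.20 and -0.12) and YAP (-0.25 and 0.071) lists, were 0.021 and 0.20 for Notch, and were -0.21 and -0.66 for heat shock genes. In these lists CRYAB, a heat shock gene, and ABCC3, a drug transporter with 62.6, 222 and 192 CPM, rose over all genes. The p53 target GDF15 had 0.769, 5.98 and 8.41 CPM (adjusted p = 0.0713).

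Lists that bear on RNA quality were not called, except for cytosolic ribosomal proteins. Those not called were mitochondrially encoded mRNAs (13 tested, median 0.12, adjusted p = 0.589), histone genes without a poly(A) tail (13 tested, median 0.18, adjusted p = 0.589) and immediate early genes (27 tested, median 0.15, adjusted p = 0.476). Ribosomal proteins were called lower by camera with a preset correlation, as given above (76 tested, median -0.18, adjusted p = 0.00337). Their median stood at percentile 9.375 of the matched random lists. With hairpin 1 and hairpin 2 the medians were 0.24 and -0.0071 for mitochondrial mRNAs, 0.57 and -0.13 for histone genes and 0.12 and 0.059 for immediate early genes. Markers of other cell types were sparse. Of the fibroblast list 6 genes were tested (median -0.19, but 0.11 with hairpin 1 and -0.00089 with hairpin 2; adjusted p = 0.241) and of the endothelial list 5 (median 1.43, adjusted p = 0.104). Endothelial TIE1 had 0.118, 3.35 and 0.666 CPM. The leukocyte and erythroid (4 tested, median 0.66, but 1.05 with hairpin 1 and -0.0048 with hairpin 2), packaging cell (3 tested, median -1.01, with -1.31 and -0.52) and hepatocyte and germ cell (1 tested, 0.77, but 1.43 and -1.10) lists were too short for the test; in the packaging cell list LHX1 had 67.3, 23.1 and 37.4 CPM, and 2 genes fell adjusted over the list alone.

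Each hairpin was also compared with the control by size alone, since 1 library against 1 has no replicate check. Of 13986 genes with a mean CPM of 1 or more, 932 were 2-fold or more higher and 266 lower with hairpin 1, and 1004 were higher and 384 lower with hairpin 2. With both hairpins 512 genes were higher and 70 lower, and 12 moved in opposite directions. In 200 simulations of unchanged libraries sharing 1 control, 119.5 genes on average were higher with both (highest 149) and 68.9 lower (highest 99). Opposite movement was simulated for 2.965 genes (highest 8), fewer than the 12 seen. The variance of the difference between hairpins was 0.2563, above the highest simulated value of 0.2548. At a mean CPM of 1 or more the 70 lower genes thus lay within the range given by the shared control. Independent lists of these sizes would share 66.9 higher and 7.30 lower genes. The log2 folds of both hairpins correlated across genes, which are not independent replicates, at r = 0.678 against 0.501 in the simulations. The covariance was 0.270 against a simulated 0.123. At a mean CPM of 10 or more, a cut chosen after the data were seen, 142 genes were higher with both (simulated 10.98, highest 19). There 19 were lower with both, above the simulated range (mean 4.615, highest 11). Because the simulations held no scatter of dispersion between genes, that range may be too narrow. The 19 genes thus do not exclude chance sharing. With 1 control library the control could not be split, and part of the excess may come from it.

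Between the hairpin libraries, 353 genes were 2-fold or more higher with hairpin 1 and 403 higher with hairpin 2. Several genes of amino acid starvation and the integrated stress response stood high with hairpin 2 and near or below the control with hairpin 1. CHAC1, a glutathione-degrading enzyme, had 4.38 CPM in the control, 4.19 with hairpin 1 and 44.1 with hairpin 2. Asparagine synthetase, encoded by ASNS, had 23.4, 17.2 and 114.9 CPM, and PCK2, a mitochondrial gluconeogenic enzyme, had 27.9, 28.2 and 168 CPM. ANKRD1 and AC006262.5 completed the 5 genes taken by rank; ANKRD1, a YAP target, had 10.9, 1.28 and 10.6 CPM. In the stress response list 16 of 35 genes were 2-fold or more higher with hairpin 2 than with hairpin 1, with a median difference of 0.94 on the log2 scale. With hairpin 1 the acute-phase gene SAA1 had 87.2 CPM against 12.8 with hairpin 2 and 6.92 in the control, and the death ligand TNFSF10 had 16.9 against 2.48 and 1.83 CPM. F2RL2, a thrombin-receptor family gene, had 16.4 CPM with hairpin 1, 1.82 with hairpin 2 and 1.24 in the control; ANGPTL4 had 12.6, 1.63 and 4.02 CPM and COL8A1 14.2, 2.12 and 2.13 CPM in the same order. Single genes were not tested between the hairpins. The ratio of CBX8 with hairpin 1 to hairpin 2 was 1.12 (95% counting interval 0.807 to 1.55).

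**Figure D4:**
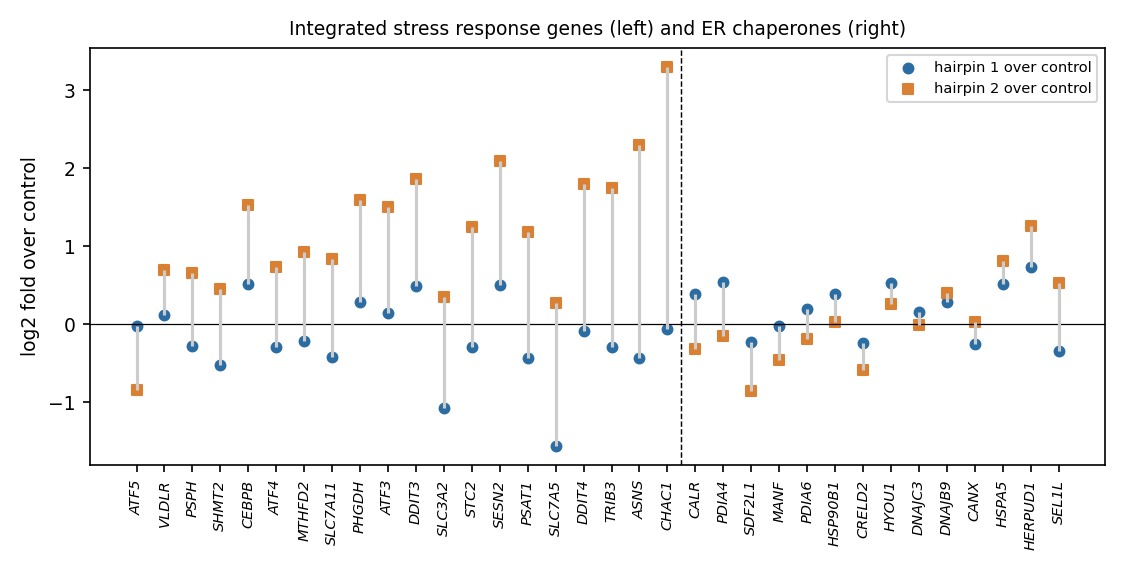
Log2 fold over the control library with hairpin 1 (circles) and hairpin 2 (squares) for integrated stress response genes, left of the dashed line, and endoplasmic reticulum chaperone genes, right of it. CHAC1 and ASNS show the widest gaps, while the chaperone genes lie on both sides of 0.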

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

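The loess correction, the mean CPM of 10 or more, the equal-weight level and the robust fit were chosen after the data were seen. The knockdown against control counts of 30 higher and 5 lower became 0 and 0 without a filter on low counts (1608 genes at an unadjusted p under 0.05), 13 and 0 at a mean CPM of 5 or more, 99 and 14 with DESeq2, 97 and 17 with the older quasi-likelihood method, 236 and 66 with the likelihood ratio test, and 0 and 0 with each of the limma fits on FPKM (2778, 3167 and 1036 genes at an unadjusted p under 0.05); library size scaling gave 2 lower. In simulations the likelihood ratio test made 8.13% false calls, the older quasi-likelihood method 4.95%, the main test 3.90% and DESeq2, over 3 simulations, 1.79%. DESeq2 called 34 of the 35 genes, RLE scaling 35, upper quartile 33, library size 28, the older method and the likelihood ratio test 35, the robust fit 29 and the mean CPM filter 13. The cause of these differences was not tested. All 35 kept their direction wherever they were tested. Upper quartile and library size scaling put the median gene at 0.11 and 0.10 on the log2 scale against 0.026, and no called list's median changed sign under RLE, upper quartile or library size scaling. With the likelihood ratio test CBX8 passed the threshold (log2 fold change -1.49, adjusted p = 0.0427) and so did SUSD2 (3.63, adjusted p = 0.00722). Neither gene passed with any other fit.

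Counts by size followed the threshold and filter by construction. For hairpin 1 the higher and lower counts were 1969 and 1216 at 1.5-fold, 199 and 26 at 4-fold, 445 and 140 at a mean CPM of 5 or more, 2506 and 1842 without a filter, and 203 and 50 on log2(FPKM + 1). For hairpin 2 they were 2262 and 1626, 145 and 12, 437 higher at a mean CPM of 5 or more, 3792 and 1774 without a filter, and 219 and 79 on log2(FPKM + 1). For both hairpins they were 1254 and 557, 77 and 4, 224 and 33, 1281 and 784, and 77 and 9 in the same order, 142 and 19 at a mean CPM of 10 or more, and 109 and 20 at an equal-weight level of 10 or more. Between hairpins they were 1197 and 1225 at 1.5-fold, 54 and 31 at 4-fold, and 152 and 167 at a mean CPM of 5 or more. On the mean of both hairpins 844 genes were higher and 202 lower. Leaving out each knockdown replicate in turn gave 932 to 1004 higher and 266 to 384 lower, and a log2 fold of 2.32 to 3.77 for SUSD2; no test is possible there for want of residual degrees of freedom. The 8 higher and 11 lower lists became 0 and 0 with an estimated correlation and with fry, tests that had little power with 1 residual degree of freedom. The stress response list had a median of -0.062 without replicate 2 and 0.65 without replicate 1, so its direction rests on hairpin 2. The epithelial median of 0.51 became 0.27 without replicate 2, the NF-kB median of 0.49 became 0.14 without replicate 1, the histone chaperone median of -0.31 became -0.52 without replicate 1, and the respiratory chain median of -0.34 became -0.22 without replicate 2. No paired analysis was possible because there was 1 control library. Depth limits weakly counted genes such as SUSD2, with 5 counts in the control.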

Other observations

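Tests of the control library standing apart, of CBX8 depth between hairpins and of genes at 0 counts in the control were written after the results were seen. The GC and length correction and the mean CPM of 10 or more were chosen after the data were seen, with bounds set before their own values were; the equal-weight level was added later, under the same bounds. After the values were seen, intervals were added to the decisions of these and the chaperone test; for the GC and CPM tests the interval also met the bound set beforehand, and for the chaperone test it did not. The split of stress genes into ATF4-linked and chaperone genes was made after the data were seen, before the chaperone values were.

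In the apoptosis list, which was not called, 10 genes were higher and 9 lower with both hairpins. Of these the pro-apoptotic genes BMF and BBC3 were higher with both hairpins, at 3.43, 15.4 and 18.4 CPM for BMF (adjusted p = 0.0554) and 2.66, 6.59 and 10.7 CPM for BBC3 (adjusted p = 0.231). The abundant chaperone HSP90AA1 had 3545 CPM in the control, 2086 with hairpin 1 and 1141 with hairpin 2, and HSPA8 had 1923, 1381 and 599 CPM. The receptor kinase gene ERBB2 had 690, 1558 and 991 CPM; none of HSP90AA1, HSPA8 and ERBB2 passed the test. Of protein-coding genes, 311 had under 10 counts in the control and 10 or more with both hairpins, and 92 showed the reverse.

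With both hairpins 512 genes were higher and 70 lower, a ratio of 7.31. The ratio was lower at 1.5-fold (1254 and 557 genes) and without a filter on low counts (1281 and 784). It was higher at 4-fold (77 and 4 genes) and on log2(FPKM + 1) (77 and 9). Simulated unchanged libraries gave 119.5 genes higher and 68.9 lower. A mean over 3 libraries lets rising genes pass more easily than falling ones; with a level that weights control and knockdown equally, at 1 CPM or more, 437 genes were higher and 77 lower (ratio 5.675), against 99.94 and 80.66 simulated. The intervals of these ratios treat genes as independent. Bias by GC content and length is argued against as the whole cause: after loess correction the ratio was 7.712 (509 and 66 genes; 95% interval 5.96 to 10.1), or 6.30 at the equal-weight level (4.89 to 8.23), where a cause would bring it to 2 or less. Counting noise of weak genes is argued against likewise, since at a mean CPM of 10 or more the ratio was 7.474 (142 and 19 genes; 4.61 to 12.8), and at an equal-weight level of 10 or more it was 5.45 (109 and 20 genes; 3.36 to 9.27), where simulated unchanged libraries gave 8.475 and 5.02 genes. A control library that stands apart for a reason other than CBX8 depletion cannot be told apart from an effect of the hairpins, because there is 1 control: 35 genes were called with the control alone against the others, and at most 1 with a hairpin library alone (113 against at most 22 with DESeq2), and 3 splits are too few for a share under 0.05. Whether the excess of higher genes reflects loss of a repressor therefore stays a hypothesis.

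One hypothesis was that genes weakly counted in the control and detected with both hairpins are classical Polycomb targets. Of 78 HOX and developmental transcription factor genes with under 10 counts in the control, 1 (DLX3) reached 10 or more with both hairpins, or 1.282% (95% exact interval 0.0325 to 6.94), against 310 of 7307 other protein-coding genes (4.24%; one-sided Fisher's exact p = 0.966). This argues against a wide release of that class of genes at this depth and degree of knockdown. The interval reaches above the share of the other genes, so a modest release is not excluded. Of genes at 0 counts in the control, 0 of 52 targets and 7 of 5050 others were detected with both hairpins. Few genes of either kind reached detection there, so those 52 targets say little. Targets with enough counts to be tested showed no general rise. Of 45 developmental factors, 9 were higher and 28 lower with both hairpins, and of 21 HOX genes 8 were higher and 6 lower.

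Integrated stress response genes were higher with hairpin 2 than with hairpin 1: 19 of 20 ATF4-linked genes, by a median of 1.36 on the log2 scale. Endoplasmic reticulum stress as the whole cause is argued against, since 14 chaperone genes had a median difference of -0.3066 (95% interval -0.63 to 0.31), below the 0.5 it would need. The median met the bound of 0.2 set beforehand, but the interval did not, and held to 0.2 it would leave this explanation open. Deeper CBX8 depletion with hairpin 2 stays open: the CBX8 level with hairpin 1 over hairpin 2 was 1.117, and its interval of 0.807 to 1.55 includes both equality and a difference. An off-target effect of hairpin 2 or a difference in culture, such as amino acid supply, was not tested.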
